A study of Escherichia coli str. K-12 substr. MG1655 with 4 samples.

How the data were processed

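The series measured RNA 5′ ends in Escherichia coli K-12 MG1655, a laboratory strain, grown in M9 minimal medium with 0.2% glucose at 30 °C to an optical density at 600 nm of about 0.6. Per the labels' protocols, rRNA-depleted total RNA was digested with 1 U of terminator exonuclease (TEX) for 60 min, an enzyme that degrades RNA with a 5′ monophosphate and spares RNA with a 5′ triphosphate, the mark of an unprocessed transcript start. A 5′ polyphosphatase then made the remaining ends ligatable, and an adapter was joined to them. The cDNA was made from random primers, size-selected to 100 to 350 bp and amplified by 13 to 17 PCR cycles before sequencing on a MiSeq. The labels list 4 libraries, 2 with the exonuclease (+TEX) and 2 without it (-TEX).

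The deposited values are one score per base and strand for each condition, a whole-number read depth that is positive on the forward strand and negative on the reverse strand. Both libraries of a condition point to the same profile, so each condition was analysed as 1 profile. The labels name a TAP profile for the -TEX libraries and a TEX profile for the +TEX libraries. The deposited profiles carry slightly different names and were matched by these abbreviations. How the libraries were combined is not given in the sources used here. The aligner and the genome build are likewise not given in the sources used here. CASAVA 1.4 is named per the submitters' processing notes, with no role given. The profiles were not scaled to a common total, and no other column of per-sample values was used.

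Read starts were estimated as the rise in depth from one base to the next along the strand, with falls set to 0. A rise is the number of reads starting minus the number ending at a base, so it is a lower bound on starts and fluctuates inside deep regions; the reads given for an end are these rises. The +TEX profile held 736701 rises and the -TEX profile 1944543. Positions with at least 10 reads over both profiles were kept, positions at most 5 nt apart were merged, and each merged end was placed at its strongest position. Ratios of +TEX to -TEX were formed after scaling to equal totals of rises, with a pseudocount of 1. An end or gene was called higher at a ratio of at least 2 and lower at a ratio of at most 0.5. Exact Clopper-Pearson intervals at 95% were computed from the reads of both profiles. They cover counting error at most. Rises are net of reads ending, and PCR copies are not independent molecules, so the intervals can be too narrow. With 1 profile per condition no difference has a replicate check, and no gene or end was tested for a difference between the conditions. The planned count test needed values per replicate and was replaced, as fixed beforehand, by ratios with counting intervals.

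Gene names came from a table of assembly ASM584v2, which has no strand and no sequence. The build of the profiles is unnamed, so the table was compared with them at its rRNA and tRNA genes. The strongest rise within 20 nt lay exactly at the table's mature 5′ end for 6 of the 7 such genes up to aspV at position 236931, and for 2 of 101 beyond it. The profiles therefore do not follow the table along the whole chromosome. Genes were named only in that first stretch, 5.11% of the covered span, with positions taken from the profiles and none converted. The earliest of these landmarks is at 223771, so the placement of genes before it rests on both numberings starting at the same base, with no landmark of its own. Ends elsewhere are given by position without a gene.

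Strand was inferred from the profiles, by a rule that was revised after the ratios had been seen. The first rule took the strand with at least 80% of the depth. The second took the strand with at least 80% of at least 50 -TEX 5′ ends inside the gene, each position counting at most 5. The third, used here, asked for 90% of at least 100 such ends and for protein-coding genes only, and rRNA and tRNA genes took the strand of their exact 5′ end. The revisions were judged partly against remembered strands, they removed most genes with high ratios, and the third rule favours genes with much -TEX signal. The rules measured 158, 85 and 54 genes in turn, of the 226 in the stretch. All 3 results are given with the gene comparison.

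A gene's reads were summed over the gene and up to 250 nt upstream on its strand, stopping at the next gene on that strand, and at least 20 reads were required. Named genes were the 10 highest and 10 lowest ratios among genes with at least 100 reads, and the 3 members with the most reads of each of 19 gene lists. Named ends were the 10 with the most +TEX reads among the higher and the 10 with the most -TEX reads among the lower. Ends of rRNA were to be left out, but rRNA genes could be recognised only in the named stretch, and all 20 named ends lie outside it, so some may be rRNA. These rules and lists were fixed before the data were examined; other items named in the text were chosen after their values were seen. A list with at least 3 measured members was compared with 10000 random lists of the same size matched on expression, and its median was given a 95% interval from 1000 Poisson resamples.

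The procedure was tested on simulated data for the comparison of ends, on 4968 ends. It recovered 99 of 100 ends simulated 4-fold higher and 99 of 100 simulated 4-fold lower, and it called 58 of 4768 unchanged ends. The simulated ends were those with at least 50 reads, at the same mean depth in both profiles, and most were unchanged. These rates therefore do not cover weaker ends, unequal depth or a majority of lower ends, all of which the real profiles have. Alternatives covered the scaling, minimum reads, pseudocount, fold rule, merge distance, gene region, strand rule and start codon window. Promoter sequence features were left out because no genome sequence was used here, and replicate agreement because each condition was 1 profile. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.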

Results

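RNA 5′ ends were profiled in exponentially growing E. coli K-12 MG1655 with (+TEX) and without (-TEX) digestion by terminator exonuclease. There were 2 libraries in each condition, analysed as 1 profile per condition. The +TEX profile held a summed depth of 56607189 bases and 736701 rises, and the -TEX profile 206346340 and 1944543. The -TEX profile was thus 2.64 times deeper in rises and 3.65 times in summed depth. Depth per rise differed, at 76.8 for +TEX and 106 for -TEX, so 2.64 need not be the ratio of read starts. None of the differences below has a replicate check, and intervals in parentheses are 95% counting intervals.

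The comparison asks which 5′ ends stay in the pool when RNA with a 5′ monophosphate is digested. Of 20714 ends, 3242 (15.7%) were higher with the exonuclease and 16285 (78.6%) were lower, while 1187 lay between. The counting interval lay wholly above a ratio of 1 for 3068 of the higher ends and wholly below it for 13885 of the lower ends. The minimum applied to unscaled reads, so ends entered more readily through the deeper -TEX profile. The higher ends took 58.0% of all +TEX reads and 6.85% of all -TEX reads. The lower ends took 5.96% and 63.1%. In the +TEX profile 34 ends held 50% of the reads, against 483 ends in the -TEX profile. Of the lower ends 12566 had no +TEX read, and of the higher ends 1049 had no -TEX read. The split depends on the settings. With median-of-ratios scaling, which adds 1.77 to every log2 ratio, 4226 ends (20.4%) were higher and 8897 (43.0%) lower. With a pseudocount of 5 instead of 1, 3315 were higher and 8178 lower. At a minimum of 1 read instead of 10 the majority turned round, with 41176 higher and 21170 lower ends. The calling rule itself favours higher ends at that minimum. With the pseudocount and the scaling, 1 +TEX read and no -TEX read is called higher, but 1 -TEX read and no +TEX read is not called.

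**Figure D1:**
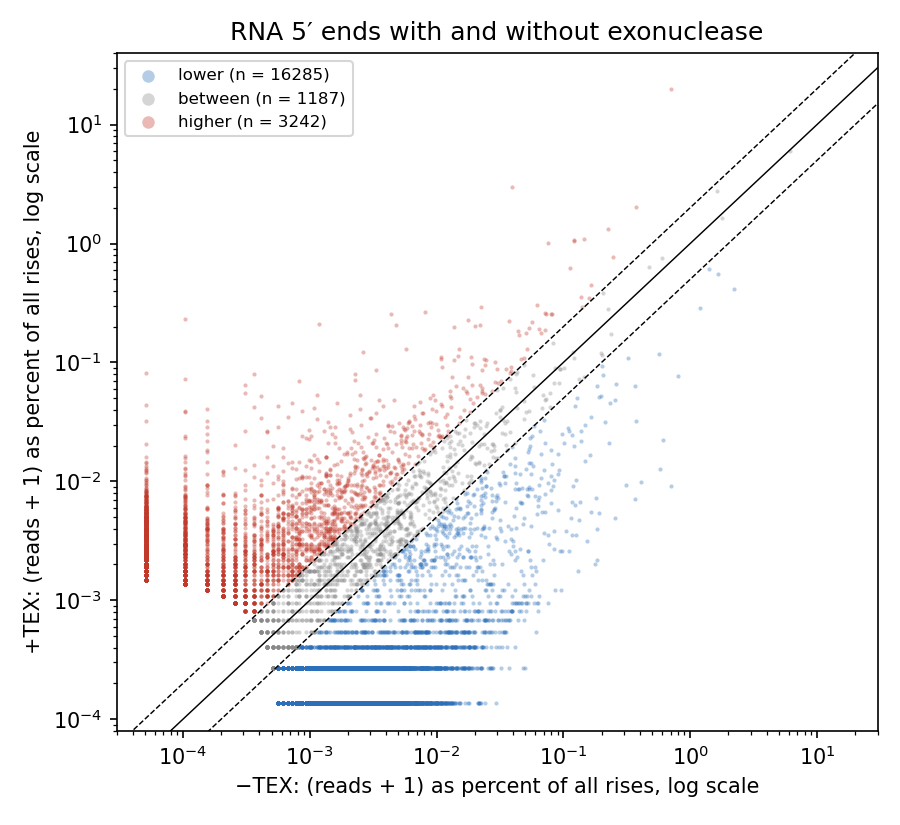
Each point is one RNA 5′ end, with its -TEX reads on the horizontal axis and its +TEX reads on the vertical axis, both as percent of all rises with 1 read added, on log scales. The solid line marks equal values and the dashed lines the 2-fold rule; 3242 ends lie above the band and 16285 below it.

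The end with the most +TEX reads was at position 3316311 on the reverse strand, with 146348 +TEX and 13706 -TEX reads, a ratio of 28.2 (27.7 to 28.7). It held 19.9% of all +TEX reads. The end at 2055403 on the reverse strand had the highest ratio among the 10 named higher ends, 76.9 (71.6 to 82.9). The forward-strand ends at 2945409, 2945519 and 2945629 lay 110 nt apart and had ratios of 7.43, 8.60 and 8.81. The other named higher ends were at 3316377, 4047922, 2051590, 2753871 and 1019409, with ratios of 13.4, 5.94, 5.61, 5.45 and 3.13. The named lower ends were led by 3054058 on the forward strand, with 42962 -TEX reads and a ratio of 0.187 (0.180 to 0.194). The ends at 2735403, 3053661 and 931654 on the forward strand had the lowest ratios among the 10 named, 0.0129, 0.0221 and 0.0242. The end with the most -TEX reads of all, 119702 at 4049059 on the forward strand, had a ratio of 0.981 and was not called. None of these ends lies in the stretch with gene names, so whether any belongs to rRNA was not determined. With median-of-ratios scaling the lower ends at 2753615 (ratio 0.334) and 3447991 (ratio 0.439) turned to log2 ratios of 0.19 and 0.58, and those at 3054058 (-0.65), 3717912 (-0.28) and 4603897 (-0.51) were no longer lower.

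In the stretch of the chromosome where genes could be named, most measured mRNAs had fewer reads with the exonuclease, relative to the totals. Among 48 protein-coding genes 42 were lower, 6 lay between and 0 were higher, with a median log2 ratio of -2.45. The lowest were leuA and leuC of leucine biosynthesis (-4.46 and -4.30), metN of the methionine transporter (-4.04), ftsZ, the ring-forming protein of cell division (-3.61), and bamA of outer membrane assembly (-3.47). They were followed by ftsQ (-3.32), carB (-3.28), aceE of pyruvate dehydrogenase (-3.25), thrC (-3.17) and secA of protein export (-3.09). The highest coding genes were carA, the small subunit of carbamoyl phosphate synthetase (0.96, but -4.20 without its upstream part), acnB, an aconitase (-0.03), ribF (-0.25), dnaE (-0.61), frr (-0.67) and metI (-0.68). The absence of higher coding genes depends on the strand rule and on scaling. Under the first rule 22 of 145 coding genes were higher and 88 lower, under the second 4 of 82 were higher and 63 lower, and all 4 of the latter (rnhA 2.12, yaaU 1.59, rluA 1.39, nhaA 1.05) were dropped by the third. The first rule also placed the rRNA gene rrfH on the reverse strand and called it higher (1.92). Its neighbours rrlH and aspU had their exact 5′ ends on the forward strand, so that rule may have taken opposite-strand reads for a gene. With median-of-ratios scaling carA, acnB, ribF, dnaE, frr and metI were higher and 19 coding genes lower. Under 3 scalings chosen after seeing the data carA alone was higher: it was at 1.27 for totals without the strongest +TEX end and at 1.43 for totals of summed depth, each with 37 coding genes lower, and at 1.54 for TMM (trimmed mean of M values), with 34 lower.

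Of the 19 gene lists, 4 had at least 3 measured members. Random lists were drawn from the 54 measured genes, list members included. Neighbouring members, such as thrA and thrB or aceE and aceF, were treated as independent, so the percentiles do not allow for shared transcripts. In amino acid biosynthesis 9 of 10 were lower, among them thrA (-2.19), thrB (-2.49) and carB (-3.28), and the list median of -2.74 (-2.91 to -2.50) was at percentile 18.0 of random lists. In glycolysis and the TCA cycle 3 of 4 were lower, with aceE at -3.25, lpd, the shared dehydrogenase subunit, at -2.53 and acnB at -0.03; the median of -2.27 was at percentile 60.5. All 3 measured sigma E members were lower, namely bamA (-3.47), surA, a periplasmic chaperone (-3.07), and lptD, the lipopolysaccharide translocon (-1.88), and their median of -3.07 was at percentile 9.84. Of 4 tRNA genes 2 were higher and 2 lower, with a median of -0.67 at percentile 97.1. The tRNA genes entered by an exact 5′ end over both profiles. Coding genes, 48 of the 54 measured, needed at least 100 -TEX ends inside them. This difference in selection favours a high percentile for the tRNA list. The tRNA median was 1.09 with median-of-ratios scaling and -0.031 with gene bodies alone. Without the strongest position of each gene neither aspU (-0.68) nor aspV (-0.13) was higher. Single members of smaller lists were rpsB of the small ribosomal subunit (-1.64) and the chaperone gene dnaK (-1.16), both lower. With median-of-ratios scaling these were at 0.13 and 0.61 and not called, and 5 of 10 amino acid biosynthesis genes, 1 of 4 in glycolysis and the TCA cycle and 2 of 3 sigma E members stayed lower, without thrA (-0.42), thrB (-0.72), lpd (-0.76) and lptD (-0.11). The pyrimidine list had carA at 0.96 and carB at -3.28, the rRNA list rrsH at -0.14 and rrlH at -0.24, and 11 lists had no measured member.

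Ends upstream of start codons and ends inside genes were compared because transcripts begin upstream. The upstream part stops at the next gene on the strand, so for genes inside an operon it need not hold a transcript start. Which genes share a transcript was not determined, so the counts of genes below may mix both kinds of upstream end. The carA end at 29551, 100 nt upstream of the start codon, had a ratio of 4.92 (4.59 to 5.29), whereas the ends inside carA had a log2 ratio of -4.20. The acnB end at 131519, 96 nt upstream, had a ratio of 3.83 (3.51 to 4.19), against -3.21 on the log2 scale inside acnB. Upstream ends of tsf, a translation elongation factor (190730, ratio 5.54), talB, a transaldolase (8110, ratio 5.12), and frr, the ribosome recycling factor (192836, ratio 3.14), were also higher while their gene bodies had log2 ratios of -3.08, -2.01 and -1.54. Several other upstream ends of carA, tsf, talB and frr were lower. At 29621 carA had 0 +TEX and 158 -TEX reads (ratio 0.0166) and at 29634 1 and 61 (ratio 0.0851). At 190803 tsf had 8 +TEX and 1856 -TEX reads (ratio 0.0128) and at 190841 a ratio of 0.0264. The talB end at 8191 had 0.0628, and frr at 192855 had 0 against 69 reads. Weaker ends were also higher, namely tsf at 190615 (19 +TEX and 0 -TEX reads) and frr at 192862 (25 and 0) and 192706 (12 and 0). Those of tsf at 190822 and frr at 192797 and 192814 were not called. The upstream ends of can, a carbonic anhydrase (142703, ratio 0.105), fabZ (202073, ratio 0.0594), aceE, thrA and ribF had lower ratios than the gene bodies. Of 14 genes with an upstream end of at least 50 reads, 9 had a higher ratio there than inside the gene. That end was the one with the most +TEX reads, a choice that favours higher ratios. Genes were also kept by the number of -TEX ends inside them, which favours lower ratios there. With the end that had the most reads over both profiles, a choice made after seeing the data, 8 of 16 genes had a higher ratio upstream, and the median upstream log2 ratio was -2.55.

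**Figure D2:**
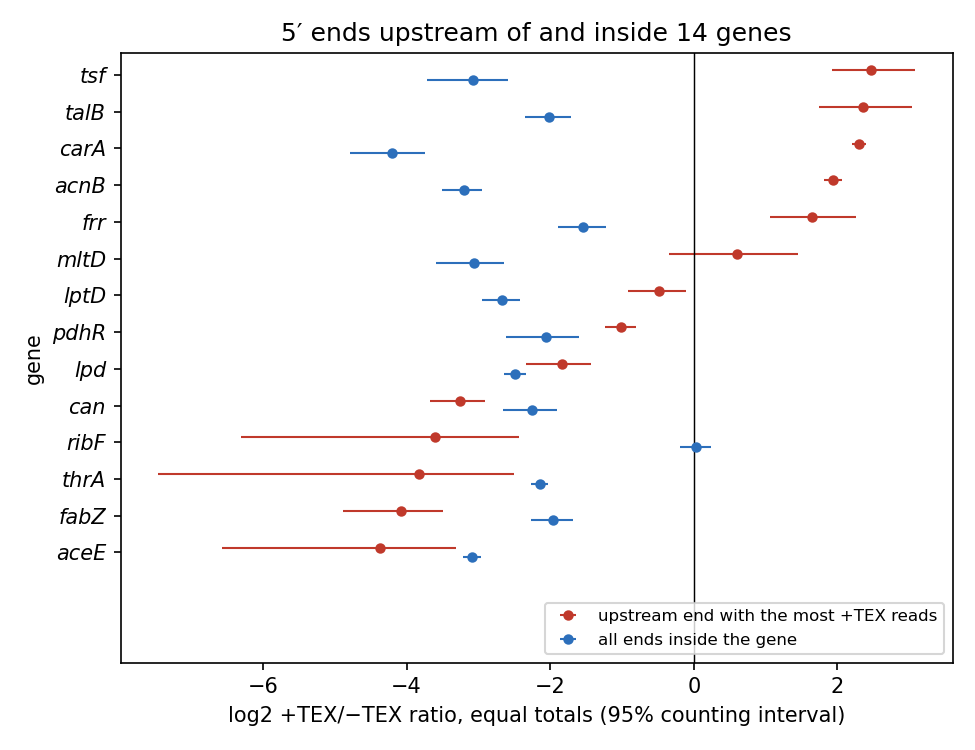
Points give the log2 +TEX to -TEX ratio, at equal totals, of the upstream end with the most +TEX reads (red) and of all ends inside the gene (blue) for 14 genes, with bars for 95% counting intervals. The plotted upstream end lies above the gene body in 9 genes, by the widest gap in carA.

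Over all such ends, 12 of 75 upstream ends (16.0%, 8.55 to 26.3) were higher, against 44 of 1166 ends inside genes (3.77%, 2.76 to 5.03). Some ends inside genes were broad and may be depth fluctuation: the lpd end at 127992 spanned 113 nt, with 6.87% of its reads at the strongest position. Requiring rises of at least 20% of the depth left 2726 higher and 10570 lower ends over both whole profiles, but was not applied here. The intervals treat ends as independent. Genes were kept for having many -TEX ends inside them, with no such demand upstream, which favours lower ends inside. Under the first and second strand rules 6.30% and 4.74% of inside ends were higher, and upstream shares under these rules were not compared. Summed over ends, the ratio was 0.799 upstream and 0.201 inside. The carA and acnB ends decide that sum: without these genes it was 0.207 (0.194 to 0.221) upstream, and 10 of 70 ends (14.3%) were higher. Among ends up to 300 nt upstream of a start codon, the 12 higher ones lay at a median of 122 nt from it and the 59 lower ones at 44 nt. Ends inside genes are not in these medians. With a window of 150 nt the medians were 98 nt for 8 higher ends and 35 nt for 51 lower ones. The window stops at the next gene on the strand, so closely spaced genes give only short distances. Some higher ends share a gene, such as those of frr and tsf. Within 5 nt upstream of a start codon there were 0 higher and 4 lower ends.

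The rRNA operon that holds rrsH and rrlH showed unequal ratios at the mature 5′ ends of its stable RNAs. The ratios of named genes here are those of the single base at the mature end, not of the merged ends used elsewhere. The 16S rRNA end of rrsH at 223771 had a ratio of 1.00 (0.695 to 1.39), the isoleucine tRNA ileV at 225381 had 0.441 (0.338 to 0.556), the alanine tRNA alaV at 225500 had 0.206 (0.0443 to 0.451), and the 23S rRNA end of rrlH at 225759 had 0.0471 (0.000597 to 0.135). As merged ends, rrsH had a ratio of 0.844 (0.639 to 1.08) and rrlH one of 0.0318. The merged end at 225346 had 12 +TEX and 1184 -TEX reads, a ratio of 0.0290. The aspartate tRNAs aspU at 228928 and aspV at 236931 had ratios of 2.16 (1.94 to 2.42) and 2.37 (2.13 to 2.63). With median-of-ratios scaling the rrsH end was higher, at a log2 ratio of 1.77, ileV was at 0.59 and alaV at -0.51, while rrlH stayed lower at -2.64. Reads from near-identical copies of these genes elsewhere in the chromosome can be placed here, so the values of single copies are uncertain.

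**Figure D3:**
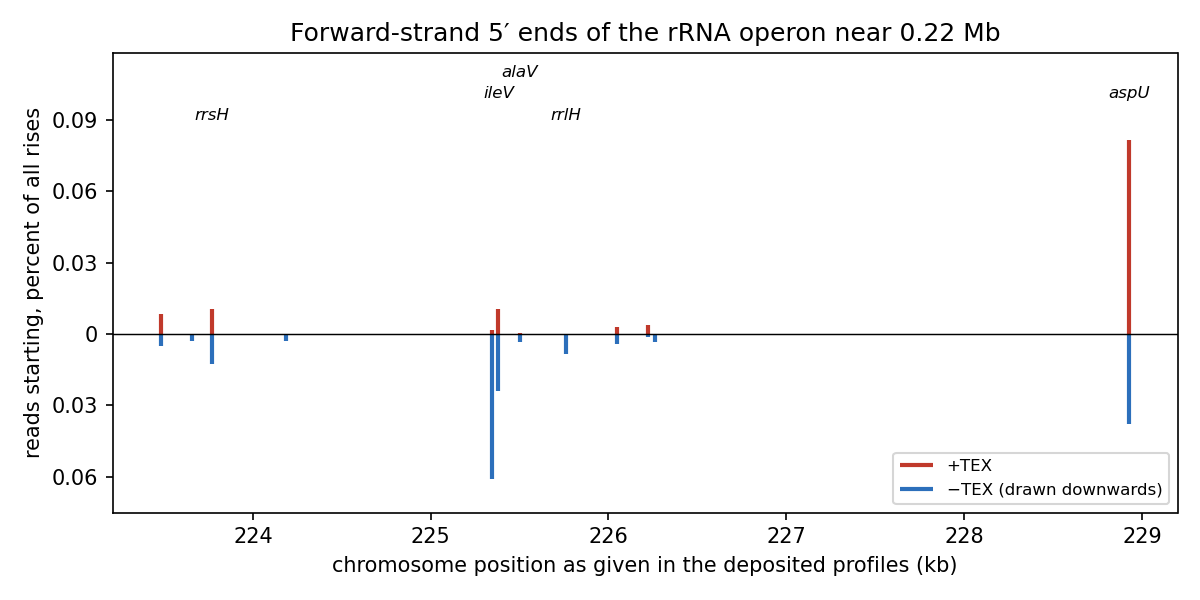
Vertical lines give the reads starting, as percent of all rises, at forward-strand ends of at least 50 reads in the rRNA operon, +TEX upwards and -TEX downwards, against the chromosome position in kb. The strongest +TEX line stands at aspU and the strongest -TEX line at 225346.

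By RNA class, rRNA genes took 2.33% (2.15 to 2.52) of the +TEX and 1.20% (1.15 to 1.25) of the -TEX reads in the stretch with gene names. There tRNA genes took 5.25% and 2.14%. The RNA had been depleted of rRNA and the cDNA size-selected, so these shares do not give the rRNA and tRNA content of the cells. The stretch itself held 3.59% of all +TEX and 8.04% of all -TEX reads, so shares within it can grow without more reads relative to the totals: of all reads of each profile, rRNA genes of the stretch took 0.0835% and 0.0965% and its tRNA genes 0.188% and 0.172%. Among the tRNA genes, aspU and aspV together took 4.87% and 1.01% of the stretch, while ileV and alaV took 0.37% and 1.13%. With gene bodies alone the -TEX shares fell to 1.04% for rRNA and 1.33% for tRNA genes, while the +TEX shares were 2.18% and 5.19%. Measured protein-coding genes took 47.4% of the +TEX and 74.4% of the -TEX reads, and the rest of the stretch, which includes genes left without a strand, took 45.0% and 22.3%.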

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

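No paired analysis was possible because each condition is one profile. The totals without the strongest +TEX end, totals of summed depth, TMM scaling, the minimum rise of 20% of the depth, the other strand rules and the other choice of upstream end were chosen after seeing the data. Among summary values 86 comparisons with an alternative stayed within the limits set for them and 37 did not. The cause was not tested, except where the setting itself moves every ratio or fixes the call of single reads. Median-of-ratios scaling, which adds 1.77 to each log2 ratio, gave 8897 lower ends, 10 higher and 19 lower genes, list medians of 1.09 for tRNA genes, -0.97 for amino acid biosynthesis, -0.50 for glycolysis and the TCA cycle and -1.30 for sigma E, and turned the ends at 2753615 and 3447991 to 0.19 and 0.58 and the genes rpsB and dnaK to 0.13 and 0.61. Totals without the strongest end (0.31 added) gave -2.43 for amino acid biosynthesis and -1.96 for glycolysis and the TCA cycle, and totals of summed depth (0.47 added) gave -2.27, -1.81 and, for sigma E, -2.60. TMM scaling (0.58 added) gave 3591 higher and 15692 lower ends and medians of -0.092 for tRNA genes, -2.16 for amino acid biosynthesis, -1.69 for glycolysis and the TCA cycle and -2.49 for sigma E, and left the ends at 2753615 (-0.999) and 3447991 (-0.61) not called; the latter was not called without the strongest end (-0.88) or with summed depth either. At a minimum of 1 read 41176 ends were higher and 21170 lower, so that most called ends were higher instead of lower. At that minimum the rule calls a lone +TEX read higher and leaves a lone -TEX read uncalled. Higher ends numbered 634 at 5 times the minimum and 6204 at a merge distance of 0 nt; lower ends numbered 2668 at 5 times the minimum, 28202 at 0 nt, 10570 with rises of at least 20% of the depth and 8178 with a pseudocount of 5. With gene bodies alone the medians were -0.031 for tRNA genes, -3.09 for amino acid biosynthesis and -2.79 for glycolysis and the TCA cycle, and the -TEX shares were 1.04% for rRNA and 1.33% for tRNA. Higher genes numbered 0 under the 4-fold rule and 0 without the strongest position of each gene, which removes the mature end and left aspU at -0.68 and aspV at -0.13. The first strand rule gave 28 higher and 92 lower genes and medians of -2.49 for amino acid biosynthesis and -1.88 for sigma E, and the second gave 4 higher genes and medians of -2.49 and -2.47. Among named genes and ends 283 values stayed within their counting interval, 192 moved outside it and 6 that had been called changed sign. Many of the 283 say little about stability. The minimum of 1 read, 5 times the minimum and the other strand rules repeated the main value of every named gene they measured. The other pseudocounts moved no named value outside its interval. Another 23 values that were not called also changed sign. Among them were metI, frr, dnaE, ribF, rrlH, rrsH and acnB under median-of-ratios scaling and carA with its gene body alone. Not run were the count tests, totals without rRNA and tRNA, the fits with replicate pairs or without a replicate, gene set tests with an estimated correlation, promoter features and replicate agreement, which need replicates, a sequence or names along the whole chromosome. Depth limits ends near the minimum of 10 reads: a count of 0 allows up to 3 reads.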

Other observations

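Several strong ends stood close together on one strand with different ratios; they were picked after the data were seen, as ends of at least 2000 reads in either profile. Of 87 such ends 16 were higher, 57 lower and 14 between, and 13 had another within 500 nt downstream. On the forward strand the end at 3053512 had a ratio of 1.86, the end at 3053661, 149 nt further, 0.0221, and the end at 3054005 had 0.0361. The reverse-strand ends at 3469083, 3469337 and 3469402 were all lower, with ratios of 0.269, 0.0965 and 0.0204, and the next one, at 3469605, had 0.897 and was not called. Some ends inside genes were higher than the gene as a whole: the end at 1460 in thrA, an aspartokinase of threonine synthesis, had 331 +TEX and 211 -TEX reads, and the end at 207634 in dnaE, the DNA polymerase III subunit, had 145 and 9.

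All tests below were chosen after the results were seen.

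The mature ends of aspU and aspV were higher while those of alaV, ileV and rrlH were lower, at equal totals. With median-of-ratios scaling the ileV end turns to 0.59 on the log2 scale, so the directions depend on scaling and the differences between ends do not. Equal resistance of mature tRNA ends to the exonuclease would give alike ratios. The log2 gap between aspU and ileV was 2.30, with the counting intervals of both aspartate tRNAs above those of ileV and alaV. These are the values that raised the question, so the gap restates the pattern and is no separate evidence on its cause. The intervals cover counting error at most and can be too narrow. Reads shared between near-identical copies may still account for the likeness of aspU and aspV, whose log2 ratios differed by 0.13; this cannot be told apart from an equal change of both, since both predict the same values. No biological explanation was tested.

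The 3 forward-strand ends 110 nt apart may be the 5′ ends of the neighbouring tRNA genes metZ, metW and metV, initiator methionine tRNA genes. In the gene table exactly 1 run of neighbouring genes has these start-to-start spacings, and it is that one; only spacings, not positions, were compared. Fluctuation of depth downstream of one strong end is argued against by the lowest share of new reads at the 3 ends, 93.9% of the depth. Near-identical copies that share reads stay open as a reason for their like ratios of 7.43, 8.60 and 8.81.

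Ends on the strand opposite to a gene were few and often higher: 13 of 19 (68.4%, 43.4 to 87.4) were higher, against 3.77% inside genes and 4.68% of inside ends with under 50 reads. Examples are the ends at 128679 within lpd, with 64 +TEX and 54 -TEX reads, and at 199936 within bamA, with 36 and 0. Sense reads placed on the wrong strand would carry the ratios of the gene. Without a minimum share on the strand, so that no gene was dropped for its opposite ends, the median log2 ratio was 1.48 opposite against -2.99 inside. The sense strand was still the one with more -TEX ends, and the medians restate the contrast. They therefore cannot decide on misplaced reads. The strand rule may itself make the pattern, because every rule tried took the sense strand from the profiles and so kept opposite strands poor in -TEX ends or in depth. The lowest share under the other rules, 59.3%, shares that selection and cannot be told apart from it; whether transcripts start within genes on the opposite strand stays open.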
